A study of Rattus norvegicus with 32 samples.

How the data were processed

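Lung RNA of 32 rat samples was measured on 2-colour spotted arrays against a common reference. Per the labels' protocols, RNA was extracted with TRI Reagent, the lung RNA of each rat was reverse transcribed and labelled, and the reference was a pool of RNA from rat organs. The protocols speak of 10 organs and name 9. Which dye marked which channel, the scanner software and the normalization are not given in the sources used here. The deposited values are log2 ratios. On the linear scale 100% of them lay within 0.001 of a multiple of 0.01, so the lowest deposited ratio was 0.01 and ratios at or below 0.05 were treated as near the floor, where a log2 value is coarse. The authors' processing could also have removed a shift of all genes between arrays, which these values cannot show.

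Each array had 13056 spots, and 12151 to 12895 of them (93.1% to 98.8%) carried a value. Of the spots 10668 had a sequence accession and 2388 had none. The 5150 accessions lay on 2 spots (5132 of them), on 4 (7) or on 34 to 36 (11). Ratios were first centred on each array's median, which had been -0.38 to 0.06 in the deposited values. Spots of 1 accession were then averaged, and spots without one were averaged as neighbouring pairs, which gave 6344 probes. Paired spots correlated at 0.623 to 0.877 within an array. Gene symbols came from the platform annotation supplied with the data: 5143 probes had 1 symbol, 7 had several and 1194 had none, and only probes with 1 symbol were named. Of 5029 Entrez identifiers 5006 were found in a table of current rat genes, and 0 spots needed a new symbol. Of the tested genes 113 had more than 1 probe; for list tests the probe with most values was used, and the text says where a named gene's probes disagree in sign.

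Groups came from the labels. The direction of the ratio was read from the genes themselves, since lung genes were higher than genes of other organs on 31 of 32 arrays. Array pairs correlated at a median of 0.602 within groups (-0.0462 to 0.79) and 0.51 between groups (-0.121 to 0.75).

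Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, statmod 1.5.0), in 1 fit over all 32 arrays and 9 groups, on the 6175 probes with a value on at least 2 arrays of every group. Adjusted p-values are Benjamini-Hochberg values over those probes within a comparison, and an adjusted p under 0.05 is a call. The 11 comparisons were each of 7 times against sham, any time (F test), the mean of the 7 times, the mean of 1, 3 and 6 h against the mean of 24, 48 and 72 h, and sham against control. Errors after a log2 change are SEs of the fit. Changes against sham rest on 3 arrays (5 at 6 h) against 6 unless stated. Gene lists were tested with camera in limma at a preset correlation of 0.01 (31 lists with at least 5 measured genes, 1 probe per gene, adjusted within a comparison). Alternatives were a correlation estimated for each list, with which 0 of the 310 list tests were called, and fry, which tests whether a list moves on balance in 1 direction. The ribosomal protein list was made from symbols and holds 1 kinase. Counts of members passing adjusted over the list alone were not corrected over the 31 lists and do not set a list against the other genes.

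The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took, in each comparison, probes with 1 symbol that were called and for which every array (or group mean) lay on the same side of the other group's mean, up to 8 in each direction by size, then up to 4 called members of each list, and the 4 with the smallest p where fewer than 4 were called. The text gives a part of these. Alb, Apob, Hp, Serpina1 and Cyp2e1, and the genes given without sham replicate 2 and 16 h replicate 3, were described after their values were seen; the latter follow the same rule in that fit. The comparisons without those 2 arrays (6112 probes) and the array axis used as a covariate were chosen after seeing the data.

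The calculation was tested on simulated data with each probe's real mean and its spread as moderated by limma, not its own residual spread. Of 6175 probes, 100 were changed by 1 log2 unit and 100 by 2 units. Noise was drawn independently for each probe, without correlation between probes and without arrays that stand apart. The shares recovered hold for such data and may differ on the real arrays. At 1, 3, 6, 16, 24, 48 and 72 h, 19%, 29%, 41%, 25%, 28%, 30% and 36% of the smaller changes were recovered, and 75%, 88%, 93%, 85%, 88%, 87% and 82% of the larger. For the mean of the 7 times 70% and 93% were recovered, for the joint test 32% and 86%, and for early against late times 74% and 95%. The joint test was simulated with the same change at all 7 times, so its shares do not cover a change at some times only. The similarity of times was set against 1000 simulated sets of unchanged groups. Alternatives tried were no centring, quantile normalization, no filter on missing values, probes with a value on all arrays (5452), only the groups compared, array weights, the replicate number as a block, sham and control joined, robust variance moderation and leaving out each array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.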

Results

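RNA from rat lung was compared with a pool of RNA from several organs on 2-colour spotted cDNA arrays, 1 array for each of 32 lung samples. Male Sprague-Dawley rats of 280 to 300 g had 40% of their estimated blood volume withdrawn through a catheter. Lungs were taken early (1, 3 and 6 h later), at 16 h and late (24, 48 and 72 h), with 5 samples at 6 h and 3 samples at each other time. A sham group of 6 samples came from rats that were instrumented but not bled, and 3 control samples came from rats without instruments. The labels do not say at which time the sham lungs were taken, so time of day may differ between sham and bled lungs. The labels speak of RNA from each rat lung without numbering the animals, so the p-values measure only the spread between these samples. Each array held 13056 spots, of which 12151 to 12895 carried a value. The number of arrays limits the precision of every comparison. The comparisons addressed how transcript levels in the lung changed with time after hemorrhage.

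Genes of the lung stood above the organ pool, and genes of liver, kidney, gut and skin, and muscle mostly below it, while brain genes lay near it (median -0.02). The median log2 ratio over 18 lung genes was higher than that over the pooled genes of 5 other organs on 31 of 32 arrays, and the sign of every ratio was read from this. Sftpc, which encodes surfactant protein C, had a mean log2 ratio of 2.80 ± 1.43 (SD, n = 32), and Scgb1a1, the secretory protein of club cells, of 2.32 ± 1.41. On sham replicate 2 liver genes were high and lung genes low. There Alb (albumin) stood at 2.62, Hp (haptoglobin) at 5.12 and Cyp2e1, a hepatic cytochrome, at 4.01, while Sftpc stood at -3.48, Sftpb at -2.38 and Scgb1a1 at -3.10. On 16 h replicate 3 most of these liver genes were high too, with Alb at 2.09, Hp at 4.62 and Serpina1 (alpha-1-antitrypsin) at 4.73, but the 2 probes of Apob (apolipoprotein B) stood at -0.80 and 1.22 against 3.24 and 2.93 on sham replicate 2. On 16 h replicate 3 Sftpc stood at 3.64 and Scgb1a1 at 2.19. Sftpb, at 0.60, and Akap5, of the type I pneumocyte genes, at -0.11, lay below each of the 30 other arrays (at least 1.29 and 1.07). The means of the 30 other arrays were -2.90 for Alb, -0.59 for Hp, 0.01 for Cyp2e1 and -0.43 for Serpina1. The median over 30 liver genes was 2.61 on sham replicate 2 and 1.99 on 16 h replicate 3, against -1.14 to 0.29 on the others. Every count of probes was therefore also taken without these 2 arrays, a choice made after the data were seen.

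**Figure D1:**
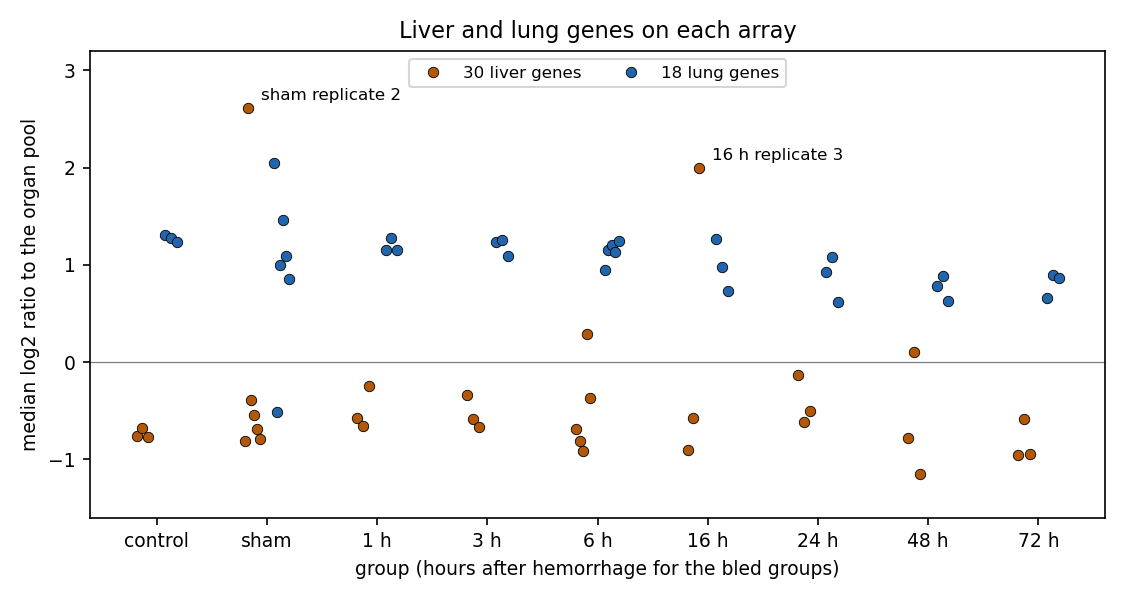
Median log2 ratio to the organ pool over 30 liver genes and 18 lung genes, 1 point per array for each set, by group (hours after hemorrhage for the bled groups). The liver median is 2.61 on sham replicate 2 and 1.99 on 16 h replicate 3, against at most 0.29 on the others, and the lung median is -0.51 on sham replicate 2 and at least 0.61 on the others.

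Instrumentation alone was examined by setting the 6 sham arrays against the 3 control arrays. The probes with the smallest p were Edn2, a member of the endothelin family of vasoconstrictor peptides, with a log2 difference of 1.46 ± 0.39 (SE), Col3a1, the chain of type III collagen, with -1.34 ± 0.36, Hcn3 with 1.36 ± 0.37 and Tgfbr3, a co-receptor for TGF-beta, with 0.85 ± 0.24. None of these was called, at an adjusted p of 0.999. The 32 genes of oxidative stress defence had a median difference of 0.28 and were shifted upward against the other genes (camera, adjusted p = 0.0242), which was lost with an estimated correlation (adjusted p = 0.698 with an estimated correlation) and without the 2 liver-rich arrays (median 0.20, adjusted p = 0.278). Within that list 0 members passed, over all probes or adjusted over the list alone. limma called 0 of 6175 probes with all arrays and 0 without the 2 arrays, while 209 and 291 had an unadjusted p under 0.05. On simulated data of this comparison, with independent noise for each probe, 25% of probes changed by 1 log2 unit and 89% of those changed by 2 units were recovered. The real arrays may differ from this.

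At 1 h after hemorrhage the 53 ribosomal protein genes, components of the translation machinery, had a median log2 change of 0.64 against sham, with 44 of the 53 above 0 (3 arrays against 6). Against the other genes this shift gave an adjusted p of 2.21e-09 with camera and an adjusted p of 0.948 with an estimated correlation. Of its members 0 passed on their own, over all probes or adjusted over the list alone. The single genes with the smallest p were Npffr2, a receptor for neuropeptide FF, with a log2 change of -1.37 ± 0.29, and Fabp2, the intestinal fatty acid binding protein, with 1.24 ± 0.28. Bloc1s1 followed with -1.27 ± 0.30 and Antkmt with -0.91 ± 0.21, all at an adjusted p of 0.27 and not called. limma called 0 probes with all arrays (464 at an unadjusted p under 0.05) and 0 without the 2 arrays (667). Without 1 h replicate 1 the count was 3.

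At 3 h, Il2, the T cell growth factor, rose by a log2 change of 2.00 ± 0.38 (adjusted p = 0.036), and Npc2, a cholesterol-carrying protein of the lysosome, by 1.81 ± 0.38 (adjusted p = 0.036; 3 arrays against 6). Without sham replicate 2, on which Npc2 stood low, its change was 1.60. Socs1, an inhibitor of cytokine signalling, changed by -2.01 ± 0.39 (adjusted p = 0.036), the only 1 of 42 cytokine, chemokine and NF-kB response genes to pass; adjusted over the list alone, 6 did. Among 42 genes of vasoactive mediators, Agt, the precursor of angiotensin, changed by -1.14 ± 0.26 (adjusted p = 0.0366) and Ptgis, prostacyclin synthase, by -0.96 ± 0.21 (adjusted p = 0.036); adjusted over the list alone, 4 did. The ribosomal protein genes had a median change of 0.97, with 48 of 53 above 0. Rpl10a rose by 2.02 ± 0.44, Rpl30 by 1.97 ± 0.45 and Rpl29 by 1.88 ± 0.42 (adjusted p = 0.036, 0.0394 and 0.0366), and 28 members passed adjusted over the list alone. The list had an adjusted p of 1.88e-14 with camera and an adjusted p of 0.929 with an estimated correlation. Clrn1, Lenep, Gpr27 and Kcnj6 changed by -2.35 ± 0.55, -1.67 ± 0.32, -1.66 ± 0.37 and -1.63 ± 0.35. All 3 h values include 3 h replicate 2, on which paired spots correlated at 0.623, the lowest of all arrays. Its median correlation with the other arrays was 0.277, against a median of 0.54 over all arrays. Lower still were sham replicate 2, at 0.095, and 16 h replicate 3, at 0.269. Paired spots of sham replicate 2 correlated at 0.647. Without 3 h replicate 2, 6 probes were higher and 16 lower.

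In all, 14 probes were higher and 15 lower at 3 h (1019 at an unadjusted p under 0.05), and without the 2 arrays 69 were higher and 113 lower. With the deposited values not centred the split was 6 higher and 10 lower, and with quantile normalization 3 higher and 13 lower. Leaving out 1 array gave counts of 1, 76, 5, 95, 18 and 0 without sham replicates 1 to 6 in order, and 75 without 3 h replicate 3. Of the 17 named genes called at 3 h, 0 kept the call through every omission of 1 array; Socs1 and Il2 each lost it in 4 of 9, with highest adjusted p-values of 0.0721 (without sham replicate 6) and 0.078 (without 3 h replicate 1). Without 3 h replicate 3 Agt stood at -0.75 (adjusted p = 0.108) and Kcnj6 at -1.08 (adjusted p = 0.097).

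At 6 h the most distinct genes had changes of about 1 log2 unit and were not called. Nt5c, a nucleotidase, stood at 1.06 ± 0.22, Gng7, a G protein subunit, at 1.04 ± 0.23, Pacsin1 at 0.90 ± 0.19, and Mdh1, the cytosolic malate dehydrogenase, at 0.79 ± 0.17 (5 arrays against 6; adjusted p = 0.0597 for each). Adjusted over the list alone, 4 of 24 apoptosis and p53 target genes, 2 of 30 hypoxia-responsive and glycolytic genes and 2 of 14 circadian clock genes passed. limma called 0 probes with all arrays (1154 at an unadjusted p under 0.05) and 0 without the 2 arrays (1147). The count was 43 without 6 h replicate 1, 17 without sham replicate 6 and 1 without sham replicate 4. Quantile normalization gave 1.

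At 16 h, Cd81, a tetraspanin of the cell surface, fell by a log2 change of 2.23 ± 0.35 (adjusted p = 0.00461), and Ube3a, a ubiquitin ligase, rose by 1.71 ± 0.32 (adjusted p = 0.0177; 3 arrays against 6). Of genes of the epithelium, Cdh1 (E-cadherin) changed by -1.73 ± 0.33 (adjusted p = 0.0203), and Napsa, a protease that processes surfactant protein B, and Muc1, a membrane mucin, by -1.24 ± 0.29 and -1.22 ± 0.31. Napsa and Muc1 were the 2 of 17 surfactant and type II pneumocyte genes to pass, and 2 passed adjusted over the list alone. Nr1d2, a repressor of the circadian clock, changed by -1.44 ± 0.31 (adjusted p = 0.0417), 1 of 14 clock genes over all probes and 4 adjusted over the list alone. Bax, which promotes apoptosis, rose by 0.91 ± 0.24 and Klrd1, a receptor of natural killer cells, by 1.22 ± 0.32 (adjusted p = 0.0485 for both). The liver genes of 16 h replicate 3 and sham replicate 2 stood beside all of these.

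With all arrays 31 probes were higher and 75 lower at 16 h, and without the 2 arrays 1 was higher and 3 lower. Of the named genes, those 4 probes held Ube3a at 1.49 (adjusted p = 0.0499), Cd81 at -2.40 (adjusted p = 0.0284) and Aldh3a2, a fatty aldehyde dehydrogenase, at -1.68 ± 0.33 (adjusted p = 0.0499). Cdh1 then had an adjusted p of 0.0548, Nr1d2 of 0.129, Napsa of 0.215, Muc1 of 0.31, Bax of 0.228 and Klrd1 of 0.256. Not centred, the split was 15 higher and 146 lower, with the median of all probes moved by -0.11, and with quantile normalization it was 1 and 5. Leaving out 1 array gave 6, 180, 5, 5 and 21 without sham replicates 1, 2, 3, 5 and 6, and 10, 211 and 4 without 16 h replicates 1, 2 and 3; Cd81 and Aldh3a2 passed in each case, and Muc1 stood at -0.78 (adjusted p = 0.296) without 16 h replicate 3.

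At 24 h, Pgf, placental growth factor of the VEGF family, rose by a log2 change of 3.28 ± 0.73 (adjusted p = 0.0166), and S100a9, a calcium-binding protein abundant in neutrophils, by 3.03 ± 0.79 (adjusted p = 0.043; 3 arrays against 6). Pgf stood at -4.77 on sham replicate 2, and without the 2 arrays its change was 2.60 (adjusted p = 0.0105). S100a9 was the 1 of 12 neutrophil genes to pass, and 2 passed adjusted over the list alone. Fcgr2a, an Fc receptor of myeloid cells, rose by 1.68 ± 0.30 (adjusted p = 0.00348), Rhag, the Rh-associated glycoprotein of red cells, by 1.45 ± 0.35 (adjusted p = 0.0306), and Ccl20, a chemokine that attracts lymphocytes and dendritic cells, by 1.10 ± 0.23 (adjusted p = 0.0117). Ccl20 and Socs1, at -1.47 ± 0.39, were the cytokine, chemokine and NF-kB response genes to pass, and 10 passed adjusted over the list alone. Camera did not call this list, and over all genes 1085 of 6175 probes had an unadjusted p under 0.05. Lower genes included Klra22, a receptor of the Ly49 family, with -2.63 ± 0.43 (adjusted p = 0.00254), Cdh1 with -1.78 ± 0.33 (adjusted p = 0.0053) and Lep (leptin) with -1.73 ± 0.32 (adjusted p = 0.0053). Plvap, which forms the diaphragms of endothelial fenestrae, changed by -1.16 ± 0.31, Ptprc (CD45, common to leukocytes) by -1.09 ± 0.29, Nr1d2 by -1.39 ± 0.31 and Jun, a subunit of AP-1, by -0.92 ± 0.23 (adjusted p = 0.0452, 0.043, 0.018 and 0.0384). The named gene with the largest fall was Cdh13 (T-cadherin), at -4.08 ± 0.81 on 2 arrays with spots near the lowest deposited ratio. The ribosomal protein genes had a median change of 0.56, with an adjusted p of 0.000334 with camera and an adjusted p of 0.989 with an estimated correlation; 0 members passed, over all probes or adjusted over the list alone.

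With all arrays 24 probes were higher and 94 lower at 24 h, and without the 2 arrays 53 and 162, where S100a9 had an adjusted p of 0.0509. Not centred, 12 were higher and 180 lower, and the median of all probes moved by -0.14. Leaving out 1 array gave 71, 70, 186 and 63 without sham replicates 1, 3, 4 and 5, and 34 without 24 h replicate 3. Cdh1, Fcgr2a and Klra22 kept their calls in each case, and Cdh13 in the 7 of 9 in which it could be tested; without 24 h replicate 1 Pgf, at 2.09, had an adjusted p of 0.132, Ccl20 of 0.0521 and S100a9, at 1.63, of 0.279, without 24 h replicate 2 Nr1d2 had 0.0566 and Jun 0.162, and without 24 h replicate 3 Lep had 0.0751, Rhag, at 0.92, 0.30, Socs1, at -0.68, 0.437 and Plvap and Ptprc 0.257.

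**Figure D2:**
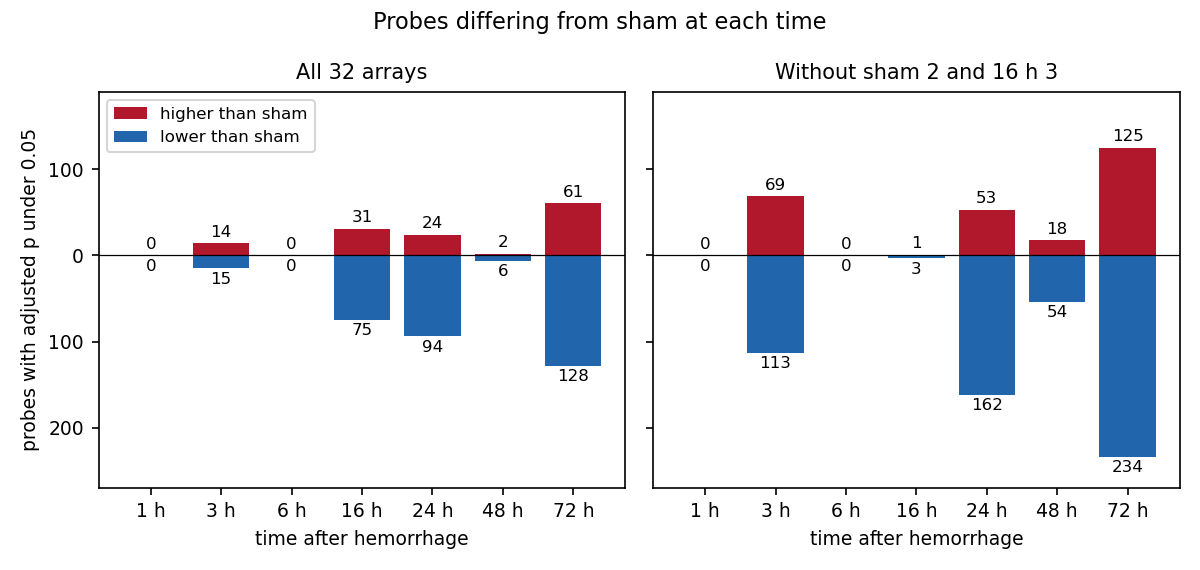
Number of probes with adjusted p under 0.05 that were higher (upward bars) or lower (downward bars) than in sham at each time after hemorrhage, with all 32 arrays and without sham replicate 2 and 16 h replicate 3. At 72 h the counts are 61 higher and 128 lower with all arrays and 125 and 234 without those arrays, and at 16 h they go from 31 and 75 to 1 and 3.

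At 48 h, Pgf rose by a log2 change of 3.45 ± 0.73 (adjusted p = 0.0485) and Ube3a by 1.71 ± 0.32 (adjusted p = 0.0279; 3 arrays against 6). Pgf stood at -4.77 on sham replicate 2, against -1.19 to 0.35 on the other sham arrays, which enlarges its change. Ifng, interferon gamma, changed by -1.26 ± 0.24, Muc2, a secreted mucin, by -1.38 ± 0.25, Tfg by -1.43 ± 0.28 and Selenom, a selenoprotein, by -1.07 ± 0.21 (adjusted p = 0.0279 for each). The 25 heat shock and chaperone genes had a median change of -0.16 and moved down on balance by fry (adjusted p = 0.00396), with 0 called over all probes and 4 adjusted over the list alone. Set against the other genes by camera, that list had an adjusted p of 0.277, and an adjusted p of 0.112 with an estimated correlation. With all arrays 2 probes were higher and 6 lower, without the 2 arrays 18 and 54, not centred 0 and 1, and with quantile normalization 29 and 87. The count was 25, 1, 20, 0 and 3 without sham replicates 2 to 6 in order and 0, 0 and 3 without 48 h replicates 1, 2 and 3; 0 of the 8 named genes passed in every case, and Ifng had an adjusted p of 0.137 without 48 h replicate 2.

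At 72 h, Mmp8, neutrophil collagenase, rose by a log2 change of 3.89 ± 0.78 (adjusted p = 0.00857), the 1 of 12 neutrophil genes to pass, with 2 adjusted over the list alone. Mcpt10, a mast cell protease, rose by 2.12 ± 0.36 (adjusted p = 0.00305), Rsad2 (viperin), 1 of 15 interferon-stimulated genes and 2 adjusted over the list alone, by 1.63 ± 0.28 (adjusted p = 0.00327), and Rhag by 1.44 ± 0.35 (adjusted p = 0.0243; 3 arrays against 6). Ube3a rose by 1.95 ± 0.32 (adjusted p = 0.00251) and Pgf by 2.93 ± 0.73 (adjusted p = 0.0248). The low value of Pgf on sham replicate 2 (-4.77) enlarges its change here too. Rsad2 stood at -1.20 on that array, against -0.36 to 0.11 on the other sham arrays. Fgfr3, a fibroblast growth factor receptor, fell by 2.21 ± 0.29 (adjusted p = 0.000228), and Hes5, a target of Notch signalling, by 2.07 ± 0.35 (adjusted p = 0.00281). Cyp4b1, a cytochrome of the lung, changed by -2.54 ± 0.54 (adjusted p = 0.0133), although its other probe stood at 0.25, and Car4, a carbonic anhydrase on lung capillaries, by -2.28 ± 0.62 (adjusted p = 0.0397).

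Among 32 genes of oxidative stress defence 2 fell at 72 h, and 3 passed adjusted over the list alone: Gpx4, which reduces lipid peroxides, by 1.65 ± 0.29 (adjusted p = 0.00327), and Gclc, of glutathione synthesis, by 1.18 ± 0.32. Hspe1, the mitochondrial co-chaperonin, changed by -1.16 ± 0.28 (adjusted p = 0.0243), 1 of 25 heat shock and chaperone genes and 2 adjusted over the list alone. That list had a median of -0.34 and moved down on balance by fry (adjusted p = 0.0151), with an adjusted p of 0.293 by camera and an adjusted p of 0.587 with an estimated correlation. Of 30 immediate early genes Jund and Fos passed, with -1.23 ± 0.34 and -0.99 ± 0.24, and 4 adjusted over the list alone. Pdk1, which slows pyruvate oxidation, and Kdr, a VEGF receptor, were the 2 of 30 hypoxia-responsive and glycolytic genes to pass, with 1.19 ± 0.33 and 0.86 ± 0.24, and 2 adjusted over the list alone. Without the 2 arrays, 7 of 43 lung epithelial genes passed as lower and 1, Cd36, as higher, with a median of -0.24 over all 43 (3 arrays against 5). Scgb1a1 changed by -2.15 ± 0.54 (adjusted p = 0.0221), Sftpc by -1.65 ± 0.49 (adjusted p = 0.0459), Sftpb by -1.50 ± 0.32 (adjusted p = 0.00822) and Fmo2, a monooxygenase abundant in lung, by -1.81 ± 0.39 (adjusted p = 0.00841). With all arrays none of these 4 passed, at -1.07, -0.53, -0.59 and -1.45 (adjusted p = 0.562, 0.802, 0.713 and 0.0726).

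With all arrays 61 probes were higher and 128 lower at 72 h, and without the 2 arrays 125 and 234. The count was 9 without 72 h replicate 3 and 23 without 72 h replicate 2. Fgfr3 and Ube3a passed in each case; without 72 h replicate 3 the adjusted p was 0.0694 for Gpx4 and 0.0511 for Hes5 and Rsad2, without 72 h replicate 2 it was 0.117 for Mmp8 and 0.0526 for Mcpt10, and the highest for the other named genes was 0.469 for Car4 without 72 h replicate 3, where its change was -0.95. Pdk1, Kdr, Gclc and Jund each lost the call in 7 of 9 cases, with adjusted p-values up to 0.211, 0.293, 0.237 and 0.291.

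Averaged over all 7 times, Cd81 changed by -1.34 ± 0.23 and Phrf1 by -1.26 ± 0.22 against sham (adjusted p = 0.00358 for both). Ccl20, at 0.72 ± 0.15, and Cxcl2, a chemokine that attracts neutrophils, at 0.88 ± 0.23, were higher (adjusted p = 0.0123 and 0.0344), as was Usp2, a deubiquitinase of the circadian system, at 1.38 ± 0.29 (adjusted p = 0.0132). Ccl20, Cxcl2 and Il18 were the 3 of 42 cytokine, chemokine and NF-kB response genes that rose, and 9 passed adjusted over the list alone; without the 2 arrays Il18 had an adjusted p of 0.142. Cdh1 changed by -1.13 ± 0.22 (adjusted p = 0.00866), Nr1d2 by -0.91 ± 0.20 (adjusted p = 0.0154) and Fn1 (fibronectin) by -0.93 ± 0.22 (adjusted p = 0.0203). The ribosomal protein genes had a median of 0.32 (adjusted p = 0.0107 with camera and an adjusted p of 0.986 with an estimated correlation), with 3 members up, 1 down and 8 passing adjusted over the list alone. Without the 2 arrays that median was 0.22 and the camera call was lost (adjusted p = 0.365). On average 112 probes were higher and 127 lower, without the 2 arrays 87 and 121, and not centred 69 and 135. The joint test of the 7 times called 144 probes, and 346 without the 2 arrays.

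Leaving out 1 array moved the count for the mean of the 7 times to 98, 96 and 95 without sham replicates 1, 3 and 5, to 378 without 3 h replicate 3 and to 158 without 72 h replicate 2. Of its 47 named genes 11 passed in every case, among them Ccl20, Cd81, Cdh1, Nr1d2 and Phrf1, and Usp2 passed in the 27 of 29 in which it was tested. Il18 lost its call in 21 of 29 (adjusted p up to 0.132), Cxcl2 in 4 (up to 0.0972) and Fn1 in 2 (up to 0.0715). The joint count went to 90 without sham replicate 3, and to 61 and 46 without 72 h replicates 2 and 3.

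Early lungs (mean of 1, 3 and 6 h) differed from late lungs (mean of 24, 48 and 72 h) in genes of several kinds. The late times are whole days after hemorrhage and the early times are not. A difference in time of day thus cannot be told apart here from time since hemorrhage. Fmo2 was higher early by a log2 difference of 1.79 ± 0.30 (adjusted p = 0.00197), Fgfr3 by 1.34 ± 0.19 (adjusted p = 0.000625) and Atp1b1, a subunit of the sodium pump, by 1.10 ± 0.24 (adjusted p = 0.0133). Gpx4 was higher early by 1.00 ± 0.19 (adjusted p = 0.00539), Hspe1 by 1.02 ± 0.18 (adjusted p = 0.00389) and Cdh1 by 1.09 ± 0.22 (adjusted p = 0.00732). Cebpb, a transcription factor of acute inflammation, at 0.84 ± 0.22, and Il6r, the interleukin 6 receptor, at 0.80 ± 0.22, were also higher early (adjusted p = 0.0325 and 0.0441). Rsad2, at -0.88 ± 0.18, and Rhag, at -1.09 ± 0.23, were higher late (adjusted p = 0.00908 for both), as were Ccl20, at -0.53 ± 0.15, and Cdk4, a kinase of the cell cycle, at -0.74 ± 0.18. Of 42 cytokine, chemokine and NF-kB response genes 2 were higher early and 1 late, and 11 passed adjusted over the list alone. The 12 erythroid and hemoglobin genes held 1 higher late, Rhag, and 3 adjusted over the list alone. The early times hold 11 arrays and the late times 9.

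**Figure D3:**
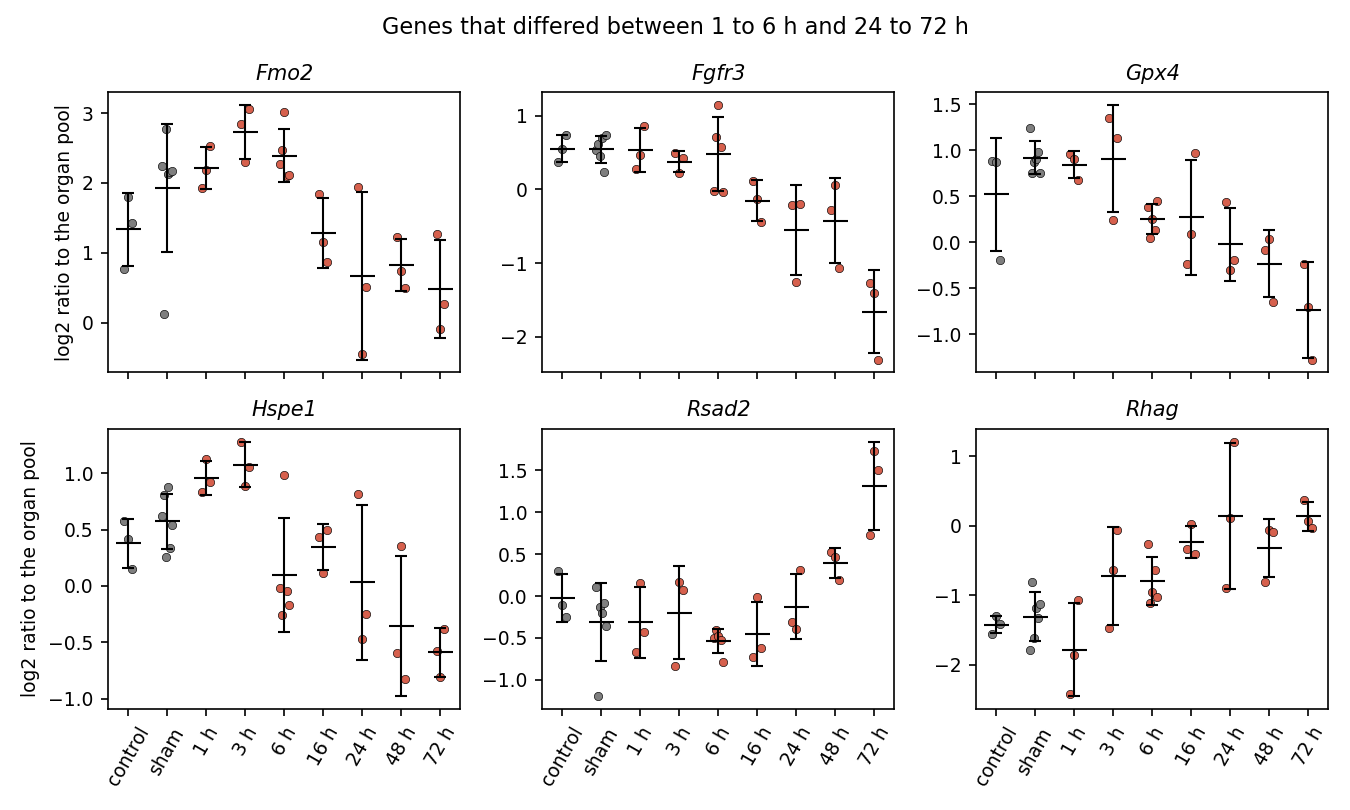
Log2 ratio to the organ pool of 6 genes that differed between early and late times, by group (hours after hemorrhage for the bled groups), with 1 point per array and bars for mean and SD. Fmo2, Fgfr3, Gpx4 and Hspe1 are lower at 24 to 72 h than at 1 to 6 h, by 1.79, 1.34, 1.00 and 1.02 on the log2 scale, and Rsad2 and Rhag are higher late (early minus late -0.88 and -1.09).

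The heat shock and chaperone genes were higher early on balance, with a median of 0.24 (fry, adjusted p = 0.000512), Hspe1 and St13 being the members called and 2 passing adjusted over the list alone; by camera the adjusted p was 0.132, and the adjusted p was 0.106 with an estimated correlation. The 16 endothelial genes had a median of 0.29 (fry, adjusted p = 0.0404; camera 0.184), with 0 called and 2 adjusted over the list alone, and an adjusted p of 0.534 with an estimated correlation. The ribosomal protein genes had a median of 0.37 (camera, adjusted p = 0.000434; adjusted p = 0.534 with an estimated correlation), with 3 members called over all probes and 3 adjusted over the list alone. In all, 124 probes were higher early and 63 higher late, and without the 2 arrays 271 and 164. The count was 104, 121 and 309 without 1 h replicate 2, 6 h replicate 3 and 24 h replicate 1, 93 without 24 h replicate 3, 109 and 110 without 48 h replicates 1 and 3, and 86 and 94 without 72 h replicates 2 and 3. Of the 46 named genes 18 passed in every case, among them Atp1b1, Cdh1, Fgfr3, Fmo2, Gpx4, Hspe1, Rhag and Rsad2; Ccl20 lost its call in 17 of 20, Il6r in 13, St13 in 11, Cebpb in 10 and Cdk4 in 3.

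The similarity of the changes at different times was examined across probes. Over the 21 pairs of times the median Pearson correlation of the changes was 0.512 (0.161 to 0.737) across 5452 probes, which are not independent, and the median Spearman correlation was 0.486. All 7 comparisons share the sham arrays. Unchanged groups were simulated from within-group deviations of arrays drawn from all groups, with a drawn set of the sham group's size as the shared control. The sham arrays themselves were not held as that control. These simulations gave a median of 0.354. Of the pairs 1, 16 and 24 h, lay above the 95% range of its simulation, and the other 20 did not. Without sham replicate 2 and 16 h replicate 3 that pair lay within its range (0.644, upper limit 0.662), and 6 and 16 h lay above (0.74, upper limit 0.691). The median covariance was 0.134 against 0.0518 simulated, a difference of 0.0822. With the sham arrays split into sets of 3 the median correlation was 0.221 (-0.213 to 0.605), and without sham replicate 2 and 16 h replicate 3 it was 0.479, against 0.383 simulated.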

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

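All tests of explanations in this part were chosen only after the results were seen, and the rule for a turned ratio was set after its values were known.

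Sham replicate 2 stood apart from the 5 other sham arrays in 7 of the 9 gene lists in which an array of the sham or 6 h group lay far from the rest. Each array was judged by its gap to the nearest other, as a share of the group's range, and chance marks about 1 in 20 groups, or 3.6 of the 72 list medians tested. The gap was 0.878 for liver genes (2.61 against at most -0.39), 0.739 for surfactant and type II pneumocyte genes (-0.97 against at least 0.44), 0.749 for brain genes, 0.691 for MHC class II genes, 0.683 for macrophage and monocyte genes, 0.658 for hypoxia-responsive and glycolytic genes and 0.628 for ion, water and fluid transport genes. At 6 h, replicate 1 stood apart in apoptosis and p53 target genes (0.751) and replicate 5 in vasoactive mediator genes (0.87).

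Of 180 tests of named genes 27 showed such a gap, 15 of them on sham replicate 2. Part of these genes were named for their values on that array or from the fit without it, so this count is no measure against chance, which marks about 1 in 20. There the gap was 0.891 for Hp, 0.88 and 0.697 for the 2 probes of Apob, 0.876 for Serpina1, 0.76 for Alb and 0.728 for Cyp2e1 (all high), 0.796 for Scgb1a1, 0.785 for Akap5, 0.779 for Sftpb, 0.759 for Fmo2, 0.717 for Sftpc, 0.70 for Pgf, 0.673 for Npc2 and 0.645 for Rsad2 (all low), and 0.643 for Bloc1s1 (high). On sham replicate 1 it was 0.886 for Lep, 0.748 for Cd36 and 0.742 for Jun, and on sham replicate 3 it was 0.74 for Aldh3a2. At 6 h it was 0.904 for Klrd1 (replicate 2), 0.81 for Hspe1 (replicate 3), 0.796 for Mcpt10 (replicate 5), 0.791 for Pdk1 and 0.721 for Hes5 (replicate 4), 0.784 for Fcgr2a (replicate 1), and for the 2 probes of Apob 0.79 (replicate 2) and 0.79 (replicate 4).

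The 2 arrays with high liver genes may hold liver RNA, and the labels say that liver was among the organs taken from each animal. On sham replicate 2 a turned ratio is argued against by skeletal muscle genes, whose median was -1.94 where a turned ratio needs a value above 0, and a mixture with a similar amount of lung RNA by Sftpc, whose difference from the mean of the other sham arrays was -6.74 log2 units where such a mixture allows about -1. Liver RNA in place of lung RNA stays open, with a median of lung genes of -0.51 against 0.61 to 2.05 on the other arrays. Its test used the high liver and low lung genes that marked the array. On 16 h replicate 3 a turned ratio is argued against by skeletal muscle genes at -1.05, and a response of the lung by the other 16 h arrays, whose highest liver median was -0.57. Liver RNA mixed into lung RNA was not tested beyond the values that marked the array (liver genes at 1.99, lung genes at 0.73). Serpina1 and Cyp2e1 stood higher there (4.73 and 4.14) than on sham replicate 2 (3.60 and 4.01), while Alb and Hp stood lower. Sftpc, at 3.64, lay above the mean of the 30 other arrays (2.98), but Sftpb and Akap5 lay below each of them. Such a mixture, and where the RNA entered, stay open.

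Ribosomal protein genes were higher at 1, 3 and 24 h in the camera test (adjusted p of 0.948, 0.929 and 0.989 with an estimated correlation, so not called there), and their median per array ran from 0.02 to 1.34 among the sham arrays alone. This may come from array differences that also occur within groups. Over 30 arrays the list median followed the main axis of within-group differences of all other probes (20.5% of that variance). The correlation was r = 0.724 (permutation p = 0.00113), with Spearman's rho = 0.743 (permutation p = 0.00042) and r = 0.722 without the 2 farthest arrays. With the axis as a covariate the difference went from 0.60 ± 0.32 to 0.28 ± 0.24 at 1 h and from 0.42 ± 0.32 to 0.14 ± 0.24 at 24 h (SE). Both lay within 2 SE of 0 before the covariate, so this step could not separate array differences from a change there. Camera with that covariate, at a preset correlation of 0.01, gave medians over the genes of 0.18 at 1 h (p = 0.015) and 0.52 at 3 h (p = 2.02e-06), and 0.21 at 24 h (p = 0.0856). At 3 h the difference went from 0.82 ± 0.32 to 0.42 ± 0.24, and to 0.46 ± 0.28 with quantile normalization. The share kept with the axis was 46.5% at 1 h, 51.6% at 3 h and 33.5% at 24 h, which sets no clear line between the times. Array differences at the 3 times, or a wider spread of ratios at 3 h, cannot be told apart as the whole cause from a change, because the errors are too large. A change in ribosomal protein transcripts after hemorrhage stays open at all 3 times.

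Without the 2 arrays, 7 of 43 lung epithelial genes were lower at 72 h (1 was higher, Cd36), with a median of -1.65 over the 7 but of -0.24 over all 43, against -0.09 over 136 genes of other cell types; with all arrays 1 was lower (Cdh1) and 1 higher, with a median of -0.20. Without the 2 arrays, 4 of those 136 were lower (Ptprc, Gata1, Ctss and Ctsd) and 3 higher (Mmp8, Rhag and Kdr). In that fit this argues against a lower share of epithelial cells with every other cell type raised alike. Of all 6112 probes in it, 234 were lower. With all arrays 1 of the 136 was lower and 4 were higher, which cannot decide this. A fall of epithelial cells together with some other cell types was not tested. Liver RNA in the 72 h samples is argued against by the median change of 28 liver genes, -0.085 (SD 0.67). The labels name 0 array batches or hybridization days, so a batch that follows the groups cannot be told apart from time, and a lower expression of these 7 genes late after hemorrhage stays open.

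Early and late changes differed for 187 probes by the contrast of both (adjusted p under 0.05). Given here are genes named at any time against sham that were also called in this contrast, and those not called are left out. The contrast uses the same bled arrays, so it is no separate support for them. The early minus late difference was 1.34 for Fgfr3 and 1.34 for Cyp4b1 (whose other probe stood at -0.22), 1.09 for Cdh1, 1.02 for Hspe1 and Lep, 1.00 for Gpx4, 0.80 for Nr1d2, 0.74 for Selenom, 0.67 for Ptprc, 0.65 for Ifng, 0.61 for Jun, 0.60 for Muc2 and 0.56 for Ctss. It was -1.25 for Clrn1, -1.09 for Rhag, -0.88 for Rsad2, -0.78 for Ube3a, -0.68 for Agt and -0.53 for Ccl20. Omitting 1 array ended this call in 17 of 20 cases for Clrn1 and Ccl20, 14 for Ctss and Ptprc, 8 for Cyp4b1, 6 for Nr1d2, 3 for Jun and 2 for Agt; for Ifng, Muc2, Selenom and Ube3a this was not recorded.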

How the results depend on the processing

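The settings without sham replicate 2 and 16 h replicate 3, and the array axis, were tests chosen only after the results were seen; the others were planned. Of the 212 calls of named genes, 172 held with quantile normalization, 169 without centring, 196 without a filter, 201 with array weights, 203 with robust moderation, 85 with only the groups compared, 120 with the replicate block and 166 without the 2 arrays; of 166 calls against sham, 69 held without sham replicate 3 and 152 without sham replicate 4. No called gene reversed in these settings. The causes were not tested except where fewer arrays or probes entered. Coarse ratios near the floor limit the precision of large falls, and of rises against a sham mean that holds such a value.

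Counts of probes that moved by over 1.5 times were these. Not centred: 16 at 3 h, 161 at 16 h, 192 at 24 h and 1 at 48 h. Quantile normalization: 16 at 3 h, 1 at 6 h, 6 at 16 h, 116 at 48 h, 416 at 72 h, 236 at any time and 344 early against late. At 48 h the count was 5 with no filter, 13 with complete probes and 5 with robust moderation. With only the groups compared, which leaves fewer arrays to estimate the spread, limma called 0 at 3, 16, 24 and 48 h and 25 at 72 h. Array weights gave 73, 378, 304, 338, 808 and 839 at 1, 3, 6, 16, 48 and 72 h, 1935 at any time, 976 for the mean, 796 early against late and 6 for sham against control. With sham and control joined it was 171, 189, 427, 324, 72 and 335 at 3, 6, 16, 24, 48 and 72 h, 460 at any time and 1063 for the mean. Without the 2 arrays it was 182, 4, 215, 72 and 359 at 3, 16, 24, 48 and 72 h, 346 at any time and 435 early against late.

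With the replicate block the count was 3 at 3 and 6 h, 0 at 48 h, 116 at 72 h, 23 at any time and 93 early against late. Over all pairs the numbers showed no pairing of the samples: the median correlation of deviations was -0.0102 over 110 same-numbered pairs and 0.00945 over 340 others. Of these pairs 29 and 97 lay above 0.1. A day or batch shared by some groups only cannot be excluded by such medians. Under the block Sftpc at 72 h was 0.29 (adjusted p = 0.917), and over the mean of the 7 times Akap5 was 0.030 and Sftpb 0.27, each the other way from its value without the 2 arrays.

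Leaving out 1 array gave 0 to 3 probes at 1 h, 0 to 95 at 3 h, 0 to 43 at 6 h, 4 to 211 at 16 h, 34 to 186 at 24 h, 0 to 25 at 48 h, 9 to 249 at 72 h, 46 to 215 at any time, 95 to 378 for the mean and 86 to 309 early against late. Sham against control stayed at 0. For the mean, Akap5 ran from -0.72 to 0.027 and Sftpb from -0.998 to 0.26. Of 310 list tests 6 were called with camera and 0 with an estimated correlation. With fry 4 were called, none of them among those 6. Without sham replicate 2 and 16 h replicate 3, camera called 4. There fry called 2 lists at 16 h, 4 at 48 h, 2 at 72 h, 6 early against late and 2 for the mean. The median correlation between times was 0.221 with the sham arrays split.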

Other observations

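All counts over other splits of the samples were tests chosen only after the results were seen. No list of fat or immune cell genes was called with camera, but single members were. Lep, at -1.73 ± 0.32 (adjusted p = 0.0053), and Fabp4, the fatty acid binding protein of adipocytes and some endothelial cells, at -1.13 ± 0.29 (adjusted p = 0.0384), were the 2 of 9 fat and mesothelial genes lower at 24 h (3 arrays against 6), and 2 passed adjusted over the list alone. Lep stood 1.02 ± 0.21 higher early than late (adjusted p = 0.0108). Ctss, a protease of antigen-presenting cells, fell by 1.07 ± 0.23 at 72 h (adjusted p = 0.014), 1 of 19 macrophage and monocyte genes, with 3 adjusted over the list alone; Ctsd, another lysosomal protease, passed only without the 2 arrays, at -1.28 ± 0.28 (adjusted p = 0.012). Cd8a, a marker of cytotoxic T cells, was higher late (early minus late -0.61 ± 0.17, adjusted p = 0.0488), 1 of 21 T and NK cell genes, with 2 adjusted over the list alone. In the circadian list Cry2 was higher late (-0.85 ± 0.22, adjusted p = 0.0309) and Nr1d2 higher early (0.80 ± 0.20, adjusted p = 0.0282), and 2 of the 14 passed adjusted over the list alone. Early and late lungs may also differ in time of day, which cannot be told apart from time since hemorrhage. Leaving out 1 array ended the call of Cd8a in 14 of 20 cases (adjusted p up to 0.122, without 24 h replicate 3), of Cry2 and Nr1d2 in 6 of 20 each (up to 0.0801 without 24 h replicate 3 and 0.066 without 72 h replicate 3), of Fabp4 at 24 h in 5 of 9 and Lep at 24 h in 1 of 9 (0.282 and 0.0751, without 24 h replicate 3), and of Ctss at 72 h in 2 of 9 (up to 0.117, without 72 h replicate 2).

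Other splits of the arrays into groups of the real sizes were counted for each comparison with at least 3 arrays in every group, with up to 100 drawn. A split cannot rank better than 1 of 84 where 84 splits exist, and the ranks were not corrected over the comparisons. They place the real groups among splits of these arrays and do not exclude chance. With all arrays, no other split called as many probes at 24 h (118 probes, as large in 1 of 84 splits, highest other 42) or 72 h (189, 1 of 84, highest other 127). The same held for any time (144, 1 of 100, highest other 14) and the mean of the 7 times (239, 1 of 100, highest other 8). It also held for early against late times (187, 1 of 100, highest other 2). Other splits called as many at 3 h (29, 5 of 84, highest other 521), 16 h (106, 8 of 84, highest other 1056) and 48 h (8, 5 of 84, highest other 39). Where 0 probes were called, every split called as many: 1 h (84 of 84, highest other 45), 6 h (100 of 100, highest other 5) and sham against control (84 of 84, highest other 147). At 3 h and at 16 h, 1 other split each called at least 5 times the real number. Which arrays made up those splits was not recorded, and the cause was not tested.

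Without sham replicate 2 and 16 h replicate 3, 2 arrays were left at 16 h and no splits were counted there. No other split called as many probes at 24 h (215, 1 of 56, highest other 166), 48 h (72, 1 of 56, highest other 11) or 72 h (359, 1 of 56, highest other 10). The same held for any time (346, 1 of 100, highest other 11) and the mean (208, 1 of 100, highest other 3). At 3 h (182, 2 of 56, highest other 449) and for early against late (435, 2 of 100, highest other 1148), 1 other split called over 2 times as many. Every split called as many at 1 h (56 of 56, highest other 3), 6 h (100 of 100, highest other 1) and for sham against control (56 of 56, highest other 7), with 0 real calls each. These ranks do not exclude chance either.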
